A study of Mus musculus with 10 samples.

How the data were processed

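Bulk RNA-seq of the aortic intima of LDL receptor knockout male mice was analysed, with 5 libraries from a low-cholesterol diet (LCD) and 5 from a high-cholesterol diet (HCD), each fed for 9 weeks. Groups and replicate numbers were taken from the labels. Total RNA was obtained by flushing the aorta with TRIzol and libraries followed standard Illumina protocols, per the labels' protocols. The authors deposited 1 table of estimated counts per gene for the 10 libraries, with 21683 gene symbols and no scaling to a common total. It was recognised as estimated counts from its values, since 58.7% of the values above 0 were not whole (tolerance 0.0005) and the library totals differed. Reads were mapped to mm10, per the submitters' processing notes. The aligner, counting program, annotation, strand setting and filters are not given in the sources used here. A program that gives estimated counts divides reads between genes with shared sequence, so genes with close relatives, pseudogenes, overlaps or antisense partners may have lost or gained reads.

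The estimated counts were rounded to whole numbers. Of the 21683 genes, 4124 were 0 in all libraries and 13659 passed edgeR's filterByExpr (minimum count 10, minimum total 15). Counts were normalised by TMM and tested for diet in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test (robust dispersion, 1 intercept and 1 diet term over all 10 libraries, no block). Genes with a Benjamini-Hochberg adjusted p below 0.05 were counted as changed. A fold change is the fitted log2 ratio of HCD to LCD, its SE is its size divided by the square root of F, and CPM is edgeR's count scaled by the TMM-adjusted library total. The common biological coefficient of variation was 0.311. Depth was 17118700 to 21584400 estimated counts per library, so 1 CPM stood for 16.3 to 21.8 counts after TMM, and the spread between libraries, not counting error, limited the precision of most genes.

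Gene lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 40 lists with at least 3 tested members. There were 18 lists of cell types, 18 of processes and 4 of RNA quality, handling and time of day. Of these, 37 were lists of symbols (441 of their 448 genes were in the table; the T cell receptor, immunoglobulin and Mx genes Trac, Trbc1, Trbc2, Ighm, Ighd, Mx1 and Mx2 were not analysed here) and 3 were taken by name pattern (ribosomal proteins, mitochondrially encoded proteins, and nuclear oxidative phosphorylation genes with their assembly factors). Some genes are shared, such as Cox8b between the brown adipocyte and oxidative phosphorylation lists, and many macrophage and foam cell genes are expressed by other leukocytes. Camera was run again with a correlation estimated for each list, and fry as a test of the list alone. The make-up of the libraries (5 technical measures and the means of the 18 cell type lists) was compared by exact two-sided permutation over all 252 assignments, where the smallest p possible is 0.00794.

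The lists, the main tests, the first set of alternatives and the rule for naming genes were fixed before the data were examined; tests and fits added later are named as such. The rule took the 6 largest rises and 6 largest falls among changed genes with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out predicted, haemoglobin, immunoglobulin, T cell receptor and small RNA genes. It also took up to 3 changed members of each list with the smallest p (for a list with none, the member with the smallest p) and Ldlr, which gave 95 genes. Genes named outside it are said to be chosen after their values were seen. Coordinates are those of GENCODE M21 (GRCm38, the assembly also called mm10), to which 21355 symbols (98.5%) matched by name.

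No pair of libraries within a group agreed within sampling noise: the chi-square per gene, which is near 1 for repeat counts of 1 library, was 38.1 to 172. Spearman correlations were 0.959 to 0.977 within LCD, 0.967 to 0.979 within HCD and 0.949 to 0.970 between diets. The labels give no batch.

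The tests were tried on counts simulated for the 13659 genes from the real means, dispersions and depths with 200 genes changed between HCD and LCD. edgeR recovered 57.0% of the 2-fold and 81.0% of the 4-fold changes, with 5.48% of its 146 calls false. DESeq2 recovered 66.0% and 89.0% with 20.9% of calls false, and limma-voom 57.0% and 77.0% with 2.19% false. These shares come from a single simulated set drawn with edgeR's own dispersion estimates, which may favour edgeR. They need not hold where more than 200 genes change. Of 3 simulated raised lists camera found 3, and it called 1 of 37 others; those simulated genes varied independently, which real list members do not.

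Alternatives were DESeq2 size factors, upper-quartile factors, no low-count filter, a filter of at least 1 CPM in at least 5 libraries, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, the replicate number as a block, each library left out in turn, a threshold of 2-fold, 1 surrogate variable (sva 3.50.0), and mitochondrial and haemoglobin genes left out. Added after seeing the data were a fit without HCD 1 and LCD 4 and fits with the smooth muscle list mean, or the average of the white and brown adipocyte list means, as a covariate. No library was left out of the main tests. The counts of changed genes and lists were also compared with 100 of the 126 splits of the libraries into 5 and 5, drawn at random with the real one included.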

Results

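RNA was sequenced from the intima, the innermost layer of the artery wall, of the mouse aorta. The mice were males lacking the LDL receptor, a background in which dietary cholesterol raises plasma cholesterol and lesions form in the aorta. They were 3 weeks old when the diets began and were fed for 9 weeks. A low-cholesterol diet (LCD) and a high-cholesterol diet (HCD) gave 5 libraries each, and the comparison asks which transcripts of these samples differ with dietary cholesterol. RNA was collected by running TRIzol, a lysis reagent, through the vessel, so a library holds RNA from every cell that the reagent reached. The deposited estimated counts summed to 17192500 to 19159000 per library in LCD and 17118700 to 21584400 in HCD. Between 14065 and 15509 genes had a value above 0 in a library. The labels number the replicates but do not say that they came from separate mice, so p-values measure only the spread between these samples, which may be technical.

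The gene removed in these mice, Ldlr (chromosome 9, 21723483 to 21749919, mm10), was near the floor in every library. Its estimated counts were 17.3 to 58.3 in the LCD libraries and 9.23 to 38.3 in the HCD libraries. The mean was 1.83 ± 0.887 CPM (counts scaled to a common library total, see above) in LCD and 1.42 ± 0.718 in HCD (SD, n = 5 each), with a log2 fold change of -0.37 (SE 0.54, adjusted p = 0.691). Both groups carry the knockout and the values are summed over the whole gene, part of which a targeted allele can still transcribe, so they do not separate the groups or test the genotype.

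Genes of macrophages and of lipid-laden foam cells rose with the high-cholesterol diet. Spp1, which encodes the secreted glycoprotein osteopontin, rose from 26.5 ± 37.7 CPM in LCD to 2447 ± 1745 CPM in HCD (SD, n = 5 each), a log2 fold change of 6.53 (SE 1.00, adjusted p = 0.000733). The other large rises were those of Clca3a2, of the calcium-activated chloride channel family (5.58, SE 0.83), Bex1 (5.16, SE 0.67), the ubiquitin ligase Rnf128 (4.95, SE 0.66), the leukocyte receptor Lilr4b (4.82, SE 0.88) and coagulation factor F7 (4.78, SE 0.68). Falls were smaller. The cation exchanger Slc24a3 fell by 2.39 on the log2 scale (SE 0.57), Smim5 by 1.70 (SE 0.32), the BMP signal transducer Smad9 by 1.59 (SE 0.33), the methyltransferase Inmt by 1.33 (SE 0.26), the retinol carrier Rbp4 by 1.30 (SE 0.23) and Rfx5, a transcription factor of MHC class II promoters, by 1.22 (SE 0.33). Spp1 lies on chromosome 5 at 104435118 to 104441050, Rnf128 on chromosome X at 139563316 to 139673145, Slc24a3 on chromosome 2 at 145167754 to 145642166 and Inmt on chromosome 6 at 55170626 to 55175043 (mm10, protein-coding genes of GENCODE M21). Estimated counts were not whole (tolerance 0.0005) in all 10 libraries for Rfx5 and Inmt, in 8 for Lilr4b, in 7 for Clca3a2, Bex1 and Slc24a3, in 6 for Spp1, in 3 for Rbp4 and in 1 for Rnf128. Reads that match several genes may have been divided there, which makes these values less certain. The call of Rfx5 was lost without LCD 1, LCD 4, LCD 5, HCD 1, HCD 2 or HCD 4, each left out alone (adjusted p = 0.0567, 0.0560, 0.0531, 0.0540, 0.0718 and 0.0553), and without HCD 1 and LCD 4 together (0.0830) or with an adipocyte marker mean as a covariate (0.176). That of Slc24a3 was lost with the replicate block (0.0545) and with the adipocyte covariate (0.181).

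Across the transcriptome, 1916 of 13659 tested genes changed (14.03%), 1385 of them higher in HCD and 531 lower. A change of at least 2-fold was found in 923 genes, of which 817 rose and 106 fell. In 1717 genes (12.6%) the CPM ranges of the diets did not overlap, where chance gives 0.794%. The first principal component held 38.2% of the variance and separated the diets, with LCD libraries from -69.3 to -31.8 and HCD libraries from 39.2 to 63.0. On the second component (15.04%), HCD 1 (-65.6) and LCD 4 (-43.8) stood apart from the rest. Without those 2 libraries, 2046 genes changed, 1370 higher and 676 lower. The number of fallen genes was less stable than the number of risen ones: it was 350 without LCD 1, 347 without HCD 2, 225 without HCD 3 and 306 without HCD 4, and without HCD 3 the total was 1275. With an adipocyte marker mean as a covariate, 988 genes changed, 808 higher and 180 lower.

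**Figure D1:**
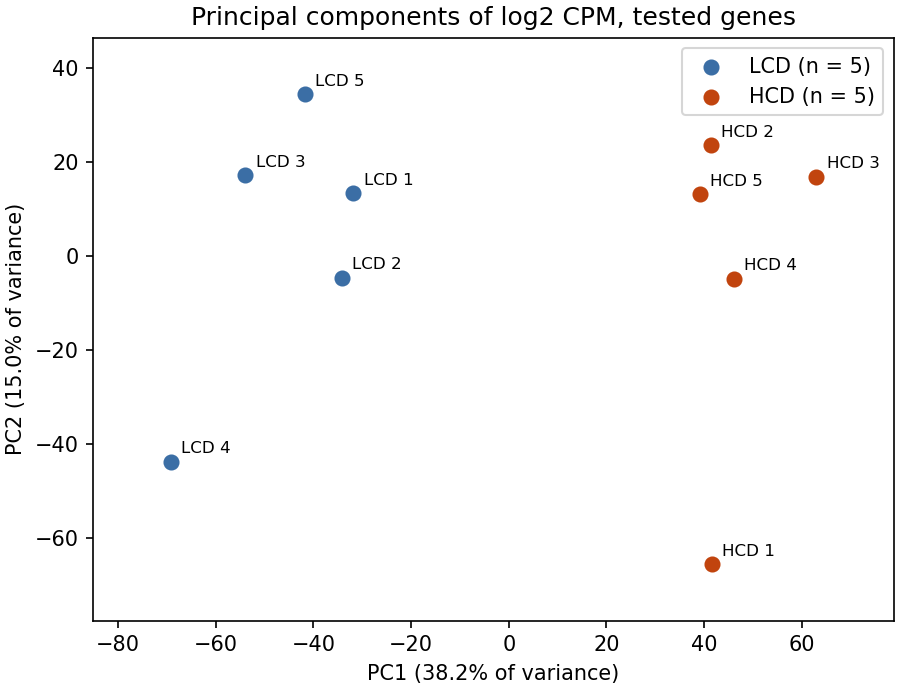
Principal components of the log2 CPM of the tested genes, with PC1 (38.2% of the variance) on the x axis and PC2 (15.04%) on the y axis, 1 point per library, 5 LCD and 5 HCD. The diets lie on opposite sides of 0 on PC1, and HCD 1 and LCD 4 lie lowest on PC2.

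Of 18 macrophage markers, 16 rose, none fell and 2 did not pass, and 16 rose when adjusted over the list alone. Cd68, a lysosomal membrane protein, rose from 48.9 ± 20.3 to 469 ± 113 CPM (log2 fold change 3.26, SE 0.28), Laptm5 from 98.4 ± 35.6 to 748 ± 130 CPM (2.93, SE 0.26) and the Fc receptor subunit Fcer1g from 40.7 ± 8.53 to 201 ± 42.9 CPM (2.30, SE 0.19; SD, n = 5 each). The list's median log2 fold change was 2.07 and its camera adjusted p was 2.84e-30 with the preset correlation and 0.0527 with an estimated correlation. Genes of Trem2-type foam cells went the same way, with 16 of 18 past the test, all higher, 2 not passing and 17 higher when adjusted over the list alone (median 2.63). Among them Ctsb and Ctsd, lysosomal proteases, rose by 2.66 (SE 0.24) and 2.60 (SE 0.23), and Lipa, which hydrolyses cholesteryl esters in the lysosome, rose by 2.26 (SE 0.20). The foam cell list had an adjusted p of 2.11e-29 with the preset and 0.0527 with an estimated correlation. All 8 genes of MHC class II antigen presentation rose, 8 also when adjusted over the list alone (median 2.01), among them Cd74 (2.08, SE 0.25), H2-Aa (2.00, SE 0.24) and H2-DMb1 (1.76, SE 0.20). That list's adjusted p was 1.89e-14 with the preset and 0.0527 with an estimated correlation. The H2 genes are related in sequence and H2-Aa and H2-DMb1 were not whole in any of the 10 libraries, so reads may be divided between them. Of 8 markers of resident, Lyve1-type macrophages, none passed in either direction. The one with the smallest p, Cbr2, had a log2 fold change of -0.51 (SE 0.22, adjusted p = 0.147). The resident list had a median of -0.40 (-0.21 without LCD 3 and -0.27 without HCD 5). Its adjusted p was 0.266 (0.759 with an estimated correlation), and it passed, lower in HCD, without LCD 1 (adjusted p = 0.0157, median -0.53). In that list 1 gene fell without LCD 1 and 1 without LCD 4.

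**Figure D2:**
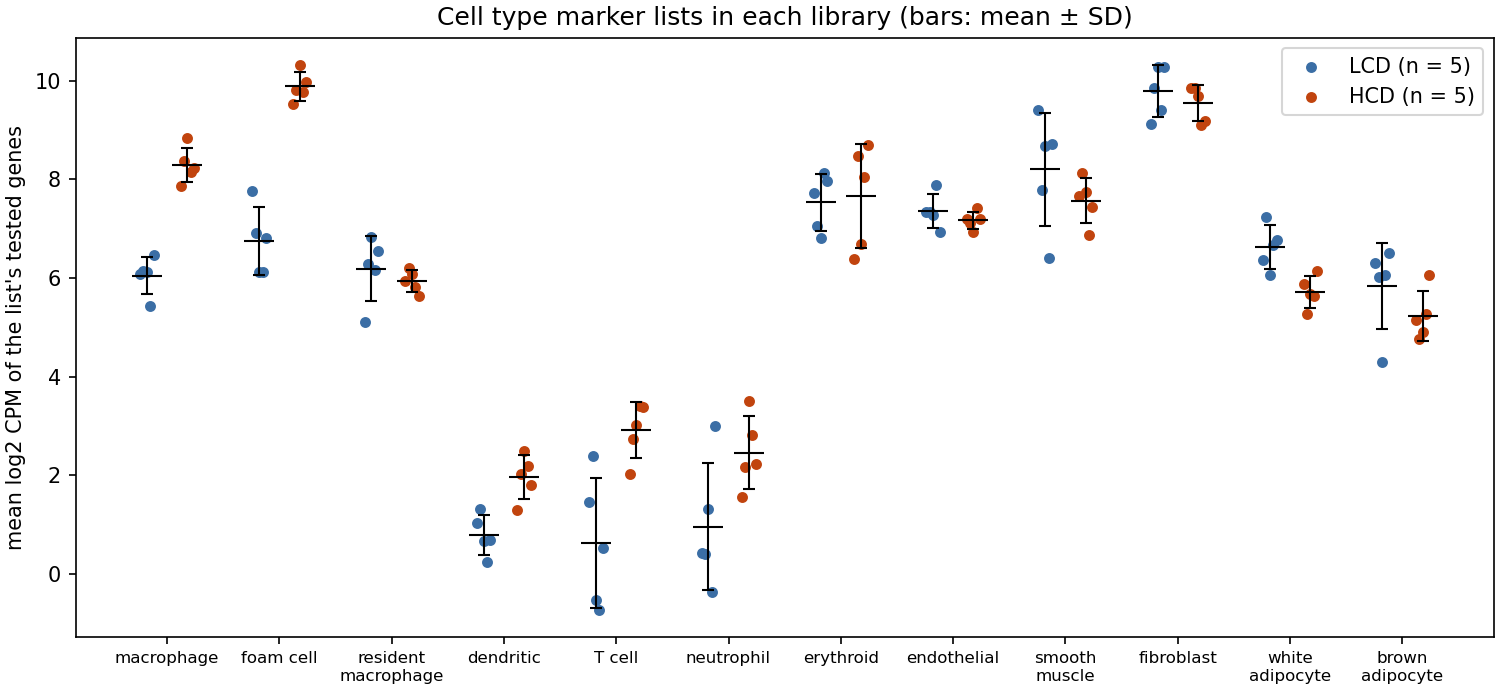
Mean log2 CPM of the tested genes of 12 cell type lists (y axis), 1 point per library, with 5 LCD and 5 HCD libraries side by side for each list (x axis) and bars for the mean and SD. The macrophage list averaged 6.05 in LCD and 8.29 in HCD with no overlap between the diets, and the endothelial list averaged 7.35 and 7.17.

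Genes of cholesterol export rose, and 4 of 22 genes of cholesterol synthesis fell, calls that were lost with the adipocyte covariate. Macrophage markers rose in the same libraries, and no fit took their list mean as a covariate. Whether the rises of export, MHC class II, inflammatory, Nrf2 and cell cycle genes only followed the macrophage markers was therefore not tested. Of 11 LXR targets and efflux genes, 6 rose, none fell and 5 did not pass, and 8 rose when adjusted over the list alone. Abcg1, an exporter of cholesterol to HDL, rose by 2.87 (SE 0.24) and lies on chromosome 17 at 31057675 to 31117988. Abca1, the exporter to lipid-poor apolipoprotein A-I, rose by 1.91 (SE 0.19) and lies on chromosome 4 at 53030787 to 53159895. Arl4c, another LXR target, rose by 1.64 (SE 0.17). The list's median was 1.10 and its adjusted p was 3.99e-11 with the preset and 0.0527 with an estimated correlation. In the cholesterol synthesis list, 4 of 22 genes fell, 1 rose and 17 did not pass, with the same counts when adjusted over the list alone. With the adipocyte covariate none of the 22 passed, and the list's median was -0.074 (adjusted p = 0.628). Insig1, the sterol-sensing partner of SCAP, fell by 0.67 (SE 0.16), Acat2 by 0.95 (SE 0.24) and the squalene epoxidase Sqle by 1.10 (SE 0.29), and the remaining 2, named after their values were seen, were Fdps (-0.55) and Mvd (1.02). Leaving out 1 library ended some of these calls: Acat2 was lost without HCD 2 (adjusted p = 0.0516) or HCD 3 (0.0544), and Sqle without LCD 1 (0.0710), LCD 2 (0.0569), LCD 4 (0.0523), HCD 3 (0.0638) or HCD 5 (0.0571). Fdps kept its call only without LCD 3, LCD 4 or LCD 5 (adjusted p up to 0.12 otherwise), and Mvd only without LCD 1, HCD 1, HCD 4 or HCD 5 (up to 0.102 otherwise). The number fallen was 2 without LCD 1, LCD 2 or HCD 2 and 1 without HCD 3. The list itself did not pass (median -0.51, adjusted p = 0.0514, 0.655 with an estimated correlation), but did without LCD 3 (0.00440), LCD 5 (0.0385) or HCD 5 (0.0266). None of 8 fatty acid synthesis genes passed; Me1 was at -1.01 (SE 0.35, adjusted p = 0.0778). That list's adjusted p was 0.134 (0.759 with an estimated correlation), and 0.00551 without LCD 3 and 0.0266 without HCD 5; 1 of its genes fell without LCD 3 or LCD 5 and 2 without HCD 5, and 1 rose without LCD 4.

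Inflammatory genes rose, and adhesion genes changed in part. Of 17 cytokine, chemokine and NF-kB genes, 10 rose (5 with the adipocyte covariate), none fell and 7 did not pass, and 12 rose when adjusted over the list alone (median 1.88). The interleukin 1 antagonist Il1rn rose from 1.52 ± 1.16 to 40.4 ± 17.1 CPM (log2 fold change 4.73, SE 0.49), the T cell chemoattractant Ccl5 from 1.76 ± 1.17 to 14.7 ± 4.54 CPM (3.06, SE 0.43) and the NF-kB inhibitor Tnfaip3 from 16.9 ± 1.69 to 46.8 ± 1.13 CPM (1.47, SE 0.11; SD, n = 5 each). The adjusted p of that list was 5.62e-10 with the preset and 0.0527 with an estimated correlation. In the list of endothelial adhesion and leukocyte recruitment, 3 of 7 genes rose and 4 did not pass, while 3 rose and 1 fell when adjusted over the list alone. The 3 were Sele (E-selectin; 1.41, SE 0.20), Cx3cl1 (fractalkine; 1.04, SE 0.18) and Selplg (2.54, SE 0.18), which encodes the selectin ligand of leukocytes and not an endothelial receptor. Of the members that did not pass, Vcam1 was at 0.37 (SE 0.21) and Icam1 at 0.03 (SE 0.16), both chosen after their values were seen. The adhesion list's median was 0.37 and its adjusted p was 0.00106 with the preset and 0.181 with an estimated correlation. Of 8 genes of the laminar flow response, 2 fell and 6 did not pass, with 2 also when adjusted over the list alone. They were the anticoagulant receptor Thbd (-0.78, SE 0.14) and the prostacyclin synthase Ptgis (-0.73, SE 0.18), and the list did not pass (adjusted p = 0.134, 0.722 with an estimated correlation) except without LCD 5 (0.0243). Of 8 Nrf2 targets, 4 rose and 4 did not pass, 4 also when adjusted over the list alone. Among them were Hmox1, which degrades haem (2.27, SE 0.25), the cystine transporter Slc7a11 (3.83, SE 0.82) and Txnrd1 (0.85, SE 0.15); the other, Srxn1 (0.56), was named after its value was seen and lost its call without LCD 2 (0.0845), LCD 3 (0.0676), LCD 4 (0.0634), HCD 3 (0.0958) or HCD 5 (0.0845). That list's adjusted p was 0.0370 with the preset and 0.225 with an estimated correlation, and the call was lost without LCD 1 (0.0877) or LCD 4 (0.0642). Of 18 interferon-stimulated genes, 3 rose and 15 did not pass, and 4 rose when adjusted over the list alone. The 3 were Oas1a (1.51, SE 0.20), Rsad2 (1.21, SE 0.24) and Stat1 (0.71, SE 0.10). The interferon list had an adjusted p of 0.0370 with the preset and 0.515 with an estimated correlation, and lost its call without LCD 1 (0.111), LCD 5 (0.0527), HCD 1 (0.0601) or HCD 2 (0.0873). Fits without 1 library added 1 fallen adhesion gene (without LCD 5), 1 risen flow gene (without LCD 4) and 1 fallen Nrf2 target (without LCD 1).

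**Figure D3:**
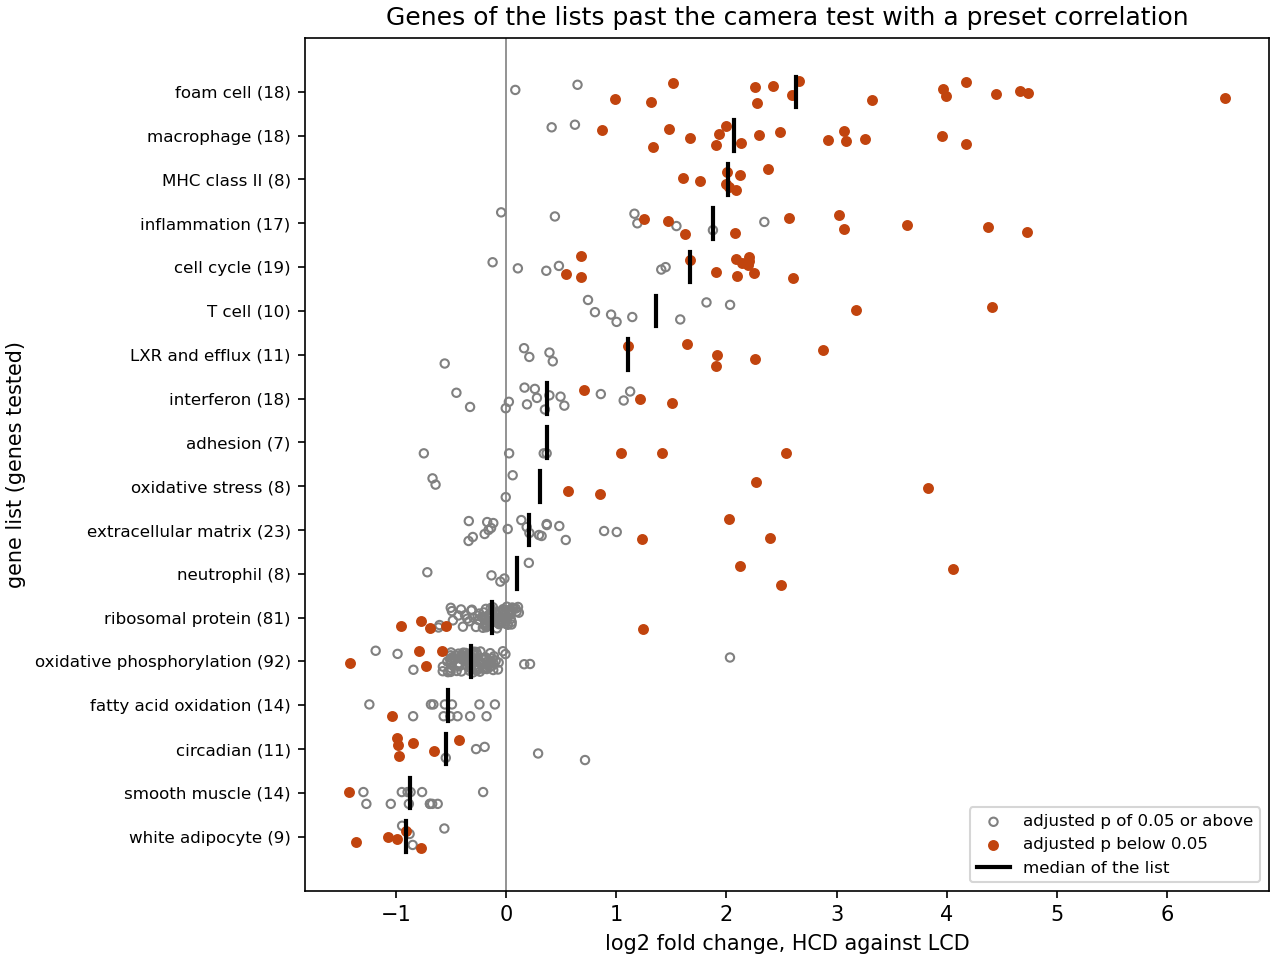
Log2 fold change of HCD against LCD (x axis) for every tested gene of the 18 lists that passed camera with the preset correlation (y axis, number of genes tested in brackets). Filled points are genes with an adjusted p below 0.05, open points the others, and black bars the list medians, which run from -0.92 for white adipocyte to 2.63 for foam cell genes.

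Cell cycle genes rose. Of 19, 13 rose (8 without HCD 3, and 3 with the adipocyte covariate), none fell and 6 did not pass, and 16 rose when adjusted over the list alone (median 1.67). With the adipocyte covariate the median was 2.03 and the list's camera adjusted p, with the preset correlation, was 6.61e-07. Top2a, the topoisomerase of dividing cells, rose from 4.62 ± 3.36 to 21.3 ± 6.21 CPM (SD, n = 5 each; 2.20, SE 0.43), Ube2c by 2.14 (SE 0.39) and the spindle factor Tpx2 by 1.90 (SE 0.26). The list's adjusted p was 1.56e-07 with the preset and 0.225 with an estimated correlation. Of 23 matrix genes, 3 rose and 20 did not pass, and 4 rose when adjusted over the list alone. Mmp14, a membrane-bound matrix protease, rose by 2.02 (SE 0.15), the vascular collagen Col8a1 by 2.40 (SE 0.24) and the protease inhibitor Timp1 by 1.24 (SE 0.35). The matrix list, with a median of 0.21, had an adjusted p of 0.0336 with the preset and 0.715 with an estimated correlation, and the call was lost without LCD 1 (0.0612), LCD 4 (0.0535) or HCD 1 (0.138). Timp1 lost its own call without LCD 1 (0.0605), LCD 2 (0.0754), LCD 4 (0.0628), HCD 2 (0.0658) or HCD 3 (0.0945). In the list of endothelial-to-mesenchymal transition, Tgfbr1 (1.18, SE 0.15) and Tgfb1 (1.14, SE 0.16) rose, 1 gene (Zeb1, -0.52, SE 0.15) fell and 11 of 14 did not pass; when adjusted over the list alone 3 rose and 2 fell. That list did not pass (adjusted p = 0.109, 0.459 with an estimated correlation), and Zeb1 lost its call in 8 of the 10 fits that left out 1 library, all but those without LCD 4 or HCD 1 (adjusted p up to 0.110). Of 7 chondrogenic and osteogenic genes, Cytl1 fell by 0.95 (SE 0.24) and 6 did not pass, with 1 fallen when adjusted over the list alone. Cytl1 lost its call without HCD 1 (0.0521) or HCD 3 (0.0528), and the list's adjusted p was 0.541 (0.759 with an estimated correlation).

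Markers of endothelial cells did not pass. Of 19 endothelial identity genes and 11 adventitial fibroblast genes none passed, while 2 endothelial genes fell without LCD 5, and 4 fibroblast genes without LCD 1 and 1 without HCD 2. Egfl7 was at -0.70 (SE 0.27, adjusted p = 0.106) and Mfap5 at -0.53 (SE 0.17, adjusted p = 0.0527). The endothelial list had an adjusted p of 0.143 (0.759 with an estimated correlation), and 0.0221 without LCD 5; the fibroblast list had the same 0.143 and 0.759, and 0.0170 without LCD 1. Of 10 T cell markers, Il7r (4.41, SE 0.66) and Cd4 (3.18, SE 0.74) rose and 8 did not pass (5 rose without LCD 2), with 3 risen when adjusted over the list alone. The T cell receptor subunit Cd3e, singled out after its value was seen, was at 1.58 (SE 0.92), and Il7r and Cd4 are also found on other leukocytes. The T cell list had a median of 1.36 (2.22 without LCD 2 and 2.71 with the adipocyte covariate) and an adjusted p of 0.00408 with the preset and 0.539 with an estimated correlation. Of 8 B cell markers only Cd22 passed (4.50, SE 0.77; 1 also when adjusted over the list alone), and the list did not (adjusted p = 0.100, 0.722 with an estimated correlation) except without LCD 5 (0.0438) or HCD 1 (0.0109). Of 8 dendritic cell markers, Ccr7 (2.90, SE 0.61), Flt3 (3.50, SE 0.77) and Cd209a (1.75, SE 0.38) rose and 5 did not pass (the 3 calls were lost with the adipocyte covariate, adjusted p = 0.0750, 0.106 and 0.106), with 3 risen when adjusted over the list alone. Over all settings run, the lowest log2 fold changes of the 3 were 2.59, 3.19 and 1.58. The dendritic median was 1.33 with the adipocyte covariate, against 1.45. The dendritic list did not pass (adjusted p = 0.0576, 0.251 with an estimated correlation), but did without LCD 2 (0.0263), LCD 4 (0.0352) or HCD 5 (0.0355). Of 8 neutrophil markers, Csf3r (2.50, SE 0.38), Mmp8 (4.06, SE 0.81) and Lcn2 (2.12, SE 0.44) rose and 5 did not pass, with 3 risen when adjusted over the list alone. The abundant granulocyte genes S100a8 (-0.02, SE 0.74) and S100a9 (-0.05, SE 0.94), chosen after their values were seen, were among the 5. The neutrophil list had a median of 0.09 and an adjusted p of 0.0370 with the preset and 0.655 with an estimated correlation, and lost its call without LCD 1 (0.0973), HCD 3 (0.0691) or HCD 4 (0.0568), and its median moved with single libraries. The neutrophil median was -0.11, 0.048, 0.052, 0.13 and 1.59 without LCD 1 to 5 and 0.32, 0.20, -0.12, 0.032 and 0.16 without HCD 1 to 5. No gene passed among 6 erythroid (adjusted p = 0.801), 6 platelet (0.425), 6 skeletal muscle (0.4997) and 5 mesothelial markers (0.810), whose estimated-correlation adjusted p values were 0.912, 0.759, 0.832 and 0.912; 1 platelet gene fell without LCD 1 and 1 without HCD 2. Mbp rose (0.93, SE 0.22) among 4 Schwann cell and neuron markers (1 also when adjusted over the list alone; list adjusted p = 0.603, 0.832 with an estimated correlation). Ryr2 fell (-1.47, SE 0.44) among 6 cardiac markers (1 also when adjusted over the list alone; list adjusted p = 0.603, 0.867 with an estimated correlation). The cardiac list's median was 0.83 (-1.004 without HCD 5) and its mean 0.49 while its test pointed lower, the mesothelial list's mean was 0.040 while its median (-0.050, but 0.16 without LCD 5 or HCD 2 and 0.0071 without HCD 1) and test pointed lower, and Ryr2 kept its call without LCD 4 or HCD 5 and lost it without any other library (adjusted p up to 0.121).

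White adipocyte markers were lower in HCD. Of 9, 5 fell, none rose and 4 did not pass, and 7 fell when adjusted over the list alone (median -0.92). Retn fell by 1.36 (SE 0.34), Cidec, of the lipid droplet, by 0.99 (SE 0.26) and Plin4 by 1.07 (SE 0.32); the other members, named after their values were seen, were Adipoq (-0.78) and Plin1 (-0.92). The adipocyte list's adjusted p was 0.00106 with the preset and 0.390 with an estimated correlation. Of 9 brown adipocyte markers, Cox8b fell (-1.42, SE 0.43) and 8 did not pass, with 0 past the threshold by edgeR when adjusted over the list alone. The brown adipocyte list did not pass (adjusted p = 0.100, 0.722 with an estimated correlation), but did without LCD 3 (0.000295) or HCD 5 (0.0238). Of 14 contractile smooth muscle genes, Synpo2 fell (-1.43, SE 0.37) and 13 did not pass, with 1 fallen when adjusted over the list alone. The smooth muscle list's median was -0.88 (-0.47 without LCD 1) and its adjusted p 0.0192 with the preset and 0.759 with an estimated correlation, and it lost its call without LCD 1 (0.111) or HCD 4 (0.0589). Of 92 nuclear genes of oxidative phosphorylation, 4 fell, none rose and 88 did not pass, and 0 passed by edgeR when adjusted over the list alone. They were Ndufa3 of complex I (-0.80, SE 0.18), Cox7c (-0.73, SE 0.19), Atp5md (-0.59, SE 0.16) and Cox8b. The list's median was -0.32 and its adjusted p 2.75e-06 with the preset and 0.722 with an estimated correlation. Of 14 fatty acid oxidation genes, the peroxisomal enzyme Ehhadh fell (-1.04, SE 0.27) and 13 did not pass, with 1 fallen when adjusted over the list alone. The oxidation list's median was -0.53 and its adjusted p 0.0103 with the preset and 0.655 with an estimated correlation; with the adipocyte covariate the median was 0.13 and the adjusted p 0.905. Of 81 ribosomal protein genes, 4 fell, 1 rose and 76 did not pass, and 0 passed by edgeR when adjusted over the list alone. Rps21 (-0.78, SE 0.18), Rps29 (-0.96, SE 0.26), Rpl39 (-0.55, SE 0.15) and, named after their values were seen, Rpl38 (-0.69) and the one that rose, Rpl10 (1.25), belong to a family with many processed pseudogenes, so their read assignment is uncertain. The ribosomal list's median was -0.13, against -0.056 for all tested genes. It was -0.057 without LCD 3, -0.20 without LCD 4, -0.039 without HCD 1, -0.20 without HCD 2 and -0.043 after the trend with gene length and GC content was removed. The ribosomal list had an adjusted p of 0.0122 with the preset and 0.824 with an estimated correlation, and the call was lost without LCD 3 (0.0974) or HCD 1 (0.140) and with the smooth muscle covariate (0.249). Among the fallen genes of these lists, the call was lost without HCD 2 or HCD 3 for Retn (adjusted p = 0.0525 and 0.0522), without HCD 4 or HCD 5 for Synpo2 (0.0555 and 0.0519), without LCD 1, HCD 3 or HCD 4 for Cox7c (0.0526, 0.0647 and 0.0544), and without LCD 3, LCD 5, HCD 3 or HCD 4 for Rps29 (0.0526 to 0.0617) and Rpl39 (0.0623 to 0.0744). Cidec lost it without LCD 2, LCD 5, HCD 1, HCD 2 or HCD 3 (0.0518 to 0.0675), Ehhadh without LCD 5, HCD 1, HCD 2, HCD 3 or HCD 4 (0.0511 to 0.0662) and Atp5md without LCD 1, LCD 5, HCD 1, HCD 3 or HCD 4 (0.0553 to 0.0879). Plin4 kept it only without LCD 4 and Cox8b only without LCD 3 or HCD 5 (adjusted p up to 0.0890 and 0.116 otherwise). Adipoq and Plin1 also kept it only without LCD 3 or HCD 5 (up to 0.116 and 0.124 otherwise). Rpl38 lost it without LCD 3, LCD 5, HCD 1, HCD 3 or HCD 4 (0.0548 to 0.0758), and Rpl10 kept it only without HCD 1 or HCD 2 (up to 0.109 otherwise). The number of fallen genes moved with single libraries. White adipocyte genes numbered 3 without LCD 1 or LCD 4, 1 without LCD 2, LCD 5 or HCD 1 and 2 without HCD 4, with none past the threshold without HCD 2 or HCD 3. Brown adipocyte genes numbered 4 without LCD 3 and 2 without HCD 5, and smooth muscle genes 8 without LCD 4. Oxidative phosphorylation genes numbered 16 without HCD 5, 2 without LCD 5 or HCD 1 and 1 without LCD 1, HCD 3 or HCD 4. Fatty acid oxidation genes numbered 6 without LCD 3, 2 without LCD 4 and 3 without HCD 5, and ribosomal protein genes 8 without LCD 4 and 1 without LCD 3, LCD 5, HCD 3 or HCD 4.

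Several circadian clock genes were lower in HCD. Of 11 circadian genes, 6 fell (3 without HCD 2, 2 without HCD 3 and 3 without HCD 5), none rose and 5 did not pass, with 6 fallen when adjusted over the list alone (median -0.55). Dbp fell from 310 ± 54.4 to 156 ± 34.5 CPM (-0.997, SE 0.17), Nr1d1 from 272 ± 19.6 to 138 ± 47.9 CPM (-0.98, SE 0.20) and Tef from 388 ± 94.2 to 247 ± 28.7 CPM (-0.65, SE 0.17; SD, n = 5 each). The clock list had an adjusted p of 0.00713 with the preset and 0.181 with an estimated correlation, and Tef lost its call without HCD 2 (0.0604) or HCD 3 (0.0632). Of 13 immediate early genes, which mark tissue handling, Egr2 (2.00, SE 0.32) and Atf3 (1.85, SE 0.52) rose and 11 did not pass, with 2 risen when adjusted over the list alone (list adjusted p = 0.603, 0.909 with an estimated correlation). No gene passed among 9 heat shock genes (list adjusted p = 0.400, 0.832 with an estimated correlation) or 13 mitochondrially encoded genes (0.672, and 0.912 with an estimated correlation; 0.0320, lower in HCD, without HCD 1). The mitochondrial list's test pointed lower while its median was 0.043 and its mean 0.015, and its median was below 0 with upper-quartile factors or no scaling factors, without LCD 3 (-0.076) or without HCD 1 (-0.40). Of 12 unfolded protein response genes, Sdf2l1 rose (1.53, SE 0.22), Trib3 fell (-0.82, SE 0.25) and 10 did not pass, with the same counts when adjusted over the list alone (list adjusted p = 0.262, 0.759 with an estimated correlation). Of 19 genes of small RNA biogenesis and tRNA modification, 3 rose, 1 fell and 15 did not pass, with the same counts when adjusted over the list alone. The ribonuclease inhibitor Rnh1 rose (1.00, SE 0.16), as did Ago4 (0.87, SE 0.22) and, named after its value was seen, Ago2 (0.55). The tRNA methyltransferase Trdmt1 fell (-0.83, SE 0.22), and the list's adjusted p was 0.916 (0.912 with an estimated correlation). The test of that list pointed lower, as did its median (-0.041, but 0.043 without LCD 4 and 0.032 without HCD 3), while its mean was 0.012. Among these genes, the call was lost without LCD 2, LCD 3 or HCD 4 for Ago4 (adjusted p = 0.0504, 0.0518 and 0.0514) and without LCD 1, LCD 3, LCD 5 or HCD 3 for Trdmt1 (0.0526 to 0.0676). Ago2 lost it without LCD 1, LCD 3, LCD 5, HCD 1, HCD 3 or HCD 4 (0.0603 to 0.0863). Atf3 kept it only without LCD 1, LCD 4 or HCD 1 and Trib3 only without LCD 2 or HCD 2 (adjusted p up to 0.0696 and 0.106 otherwise). Without 1 library, 3 unfolded protein response genes rose (without HCD 5), 1 small RNA gene rose (without LCD 3, or without HCD 4), 1 immediate early gene fell (without LCD 5), and 1 mitochondrially encoded gene rose (without LCD 4) or fell (without HCD 1).

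**Figure D4:**
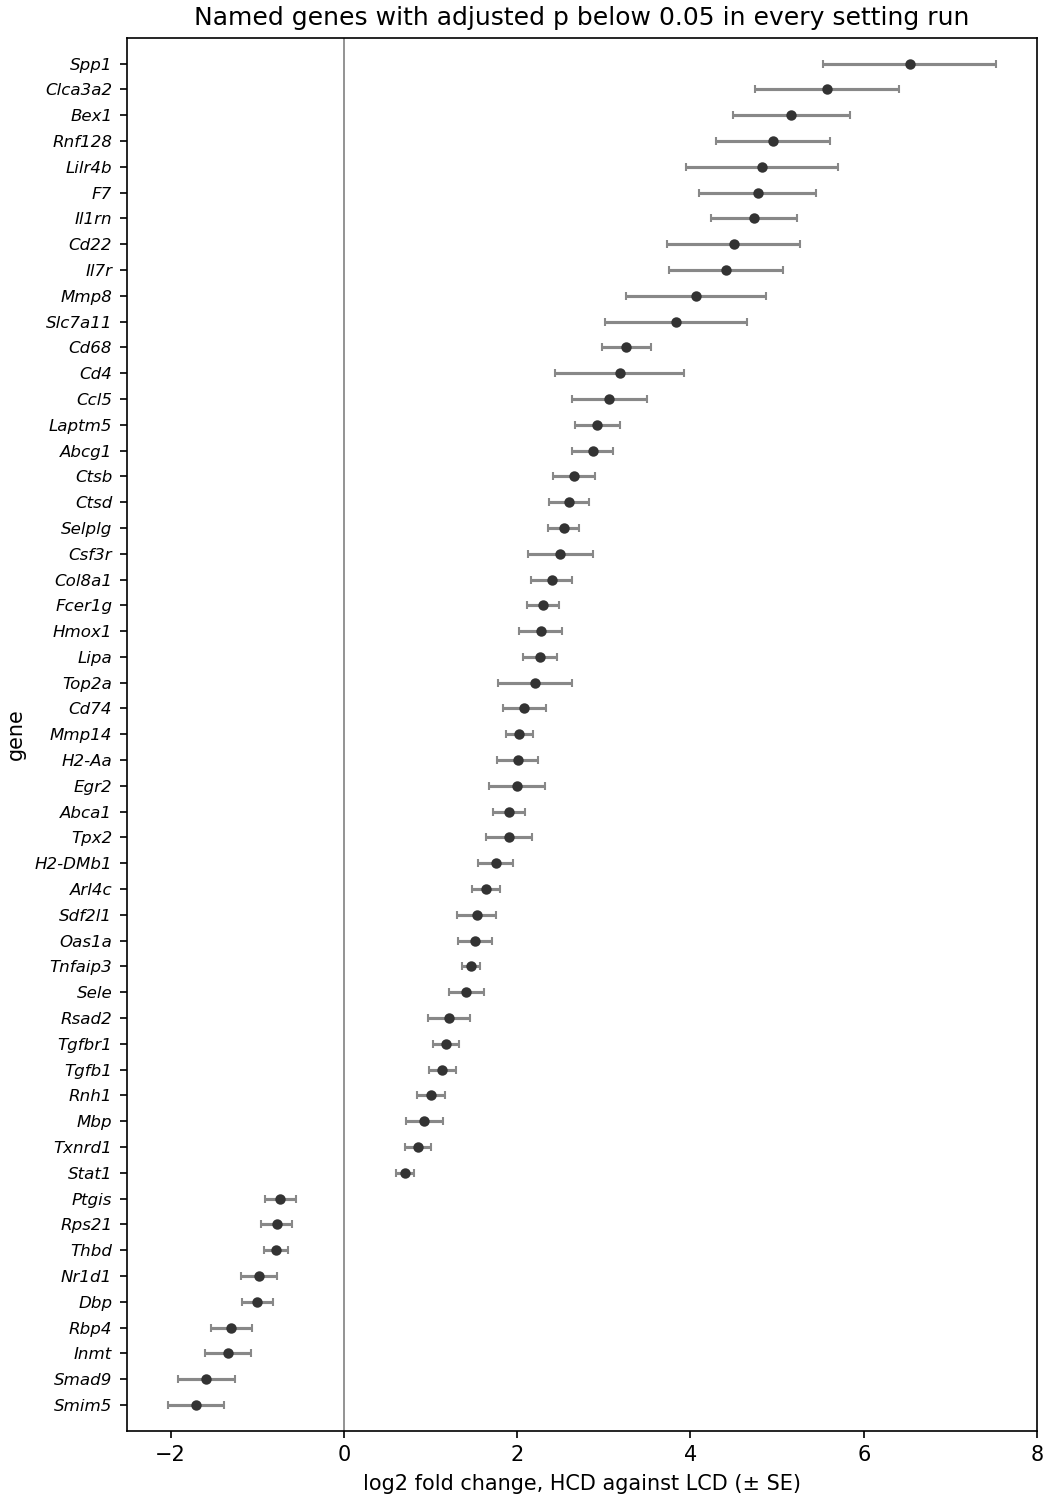
Log2 fold change of HCD against LCD (x axis; point and SE, n = 5 each) for the 53 named genes (y axis) with an adjusted p below 0.05 in every setting run (the 2-fold threshold not applied). They run from -1.70 for Smim5 to 6.53 for Spp1.

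The make-up of the libraries was compared by exact two-sided permutation tests over all 252 assignments, whose smallest possible p is 0.00794. The mean log2 CPM of the macrophage markers was 6.05 ± 0.37 in LCD and 8.29 ± 0.35 in HCD, and that of the foam cell genes 6.75 ± 0.69 and 9.89 ± 0.29 (SD, n = 5 each; exact p = 0.00794 for both). The white adipocyte mean was 6.62 ± 0.45 and 5.72 ± 0.33, the T cell mean 0.62 ± 1.32 and 2.92 ± 0.57 and the dendritic mean 0.78 ± 0.41 and 1.96 ± 0.45 (SD, n = 5 each; exact p = 0.0159 for each). The difference between the diets was -0.19 for endothelial genes (exact p = 0.349), -0.63 for smooth muscle genes (exact p = 0.278) and 0.13 for erythroid genes (exact p = 0.802). Adventitial fibroblast genes averaged 9.79 in LCD and 9.54 in HCD and smooth muscle genes 8.20 and 7.57. Both lay above endothelial genes, at 7.35 and 7.17, so the samples were not of endothelial RNA alone. Means of different genes do not measure amounts of cells. After adjustment 0 of the 23 measures passed, 5 passed unadjusted, and the smallest adjusted p was 0.0730. The macrophage and foam cell means, already at the smallest p possible, could not pass over 23 measures unless more measures had a p at or near it. The adjusted result therefore does not show that the make-up was alike. Without HCD 1, 4 passed, the macrophage, foam cell, dendritic and B cell means (adjusted p = 0.0456). Mitochondrial transcripts made up 8.33 ± 1.78% of the counts in LCD and 7.999 ± 4.04% in HCD (SD, n = 5 each; exact p = 0.897), with 14.9% in HCD 1, and haemoglobin transcripts 0.531 ± 0.197% and 0.693 ± 0.487% (SD, n = 5 each; exact p = 0.508).

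In all, 18 of the 40 lists passed camera with the preset correlation, 12 higher and 6 lower in HCD, 14 passed fry (12 of these 18, and 2 others, the dendritic and endothelial-to-mesenchymal lists), and with an estimated correlation 0 passed camera, 8 at an unadjusted p. At least 18 lists were called in 35 of 100 splits of the libraries into 5 and 5, the real split among the 35. The number of lists therefore does not set the diets apart from other groupings of the libraries. With the adipocyte covariate the calls of the oxidative phosphorylation (adjusted p = 0.170), white adipocyte (0.125), fatty acid oxidation (0.905), matrix (0.611), interferon (0.141), neutrophil (0.0655) and Nrf2 lists (0.0871) were lost, and the resident macrophage (0.0315), fibroblast (0.00884) and immediate early lists (0.00163) passed, lower in HCD. The medians of the 7 lists that lost their calls, in that order, were -0.040, -0.39, 0.13, 0.083, 0.29, 0.87 and 0.32. In the main fit they were -0.32, -0.92, -0.53, 0.21, 0.37, 0.09 and 0.31, so the neutrophil and Nrf2 medians were not lower with the covariate. With the smooth muscle covariate the ribosomal (0.249), smooth muscle (0.726) and interferon lists (0.0752) lost their calls, and the endothelial (0.0148) and cholesterol synthesis lists (0.0296, but 0.628 with the adipocyte covariate), lower, and the endothelial-to-mesenchymal list (0.0427), higher, passed. Of the named genes past the threshold, 29 lost their call with the adipocyte covariate. Of the 84 named genes past the threshold, 62 stayed past it without each library in turn and 22 did not (adjusted p = 0.0504 to 0.121 where lost); the number lost was 11, 9, 9, 5 and 13 without LCD 1 to 5 and 9, 12, 19, 14 and 6 without HCD 1 to 5.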

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

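The tests against erythroid and endothelial genes and the counts of splits for single lists were chosen after the results were seen, and the covariate fits were added after the data were seen but before their own results; Hbb-bs, Cfd and Pck1 were chosen after their values were seen. In 280 comparisons within groups of 5 libraries, 23 had a library whose gap to its nearest neighbour was over 0.71 of the group's range. Chance gives about 1 in 20, or 14, and related measures repeat each other.

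Each value below is followed by the range of the other 4 libraries of its diet, in log2 CPM for lists and genes, and by its gap. LCD 3 was low in the mitochondrial share (5.19%, the others 8.60 to 9.42%; 0.805), the share of the 10 highest genes (7.14%, 9.88 to 10.5%; 0.824), the mitochondrially encoded list (11.23, 11.95 to 12.09; 0.835), the brown adipocyte list (4.30, 6.03 to 6.50; 0.785), fatty acid oxidation (5.87, 6.75 to 7.09; 0.717) and Cox8b (5.38, 7.26 to 7.85; 0.760). HCD 1 was high in the share of the 10 highest genes (15.3%, 9.37 to 10.4%; 0.818), the nerve list (3.52, 2.53 to 2.75; 0.783) and Zeb1 (6.67, 6.06 to 6.23; 0.714), and low in the B cell list (-1.26, 1.12 to 1.93; 0.746). HCD 5 was high in the cardiac list (4.08, 0.31 to 1.05; 0.803), fatty acid oxidation (6.74, 6.07 to 6.13; 0.915) and Cox8b (6.93, 5.16 to 5.66; 0.715). LCD 4 was low in the endothelial-to-mesenchymal list (5.92, 6.23 to 6.33; 0.765), the Nrf2 list (3.89, 4.29 to 4.42; 0.759) and Ccr7 (-3.22, -0.37 to 0.050; 0.871). HCD 3 was high in Spp1 (12.44, 10.59 to 10.80; 0.885) and the cell cycle list (3.72, 3.30 to 3.39; 0.798), HCD 2 in heat shock genes (8.43, 7.21 to 7.44; 0.811) and LCD 5 in Lcn2 (4.05, 1.72 to 2.39; 0.713). LCD 5 was low in the flow list (7.38, 8.18 to 8.5004; 0.712), LCD 2 in Dbp (7.77, 8.28 to 8.48; 0.715) and LCD 1 in Pf4 (5.21, 6.45 to 6.81; 0.778).

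An arbitrary grouping of these libraries is argued against for the number of changed genes. Of 100 splits (of 126 possible) only 1, the real one, gave 1916, and the highest other split gave 152. Every other split mixes the diets, which widens the spread within its groups and lowers its count. The labels do not say that the libraries came from separate mice, so a difference between few animals or pools is not excluded. Chance cannot be excluded for the number of changed lists: 35 of 100 splits, the real one among them, gave 18 or more, and the highest other split gave 26. Genes of a cell type rise and fall together between libraries of 1 diet, with an estimated correlation of 0.577 between macrophage markers, against the preset 0.01.

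Macrophage and foam cell genes were higher in HCD (16 of 18 in each list), although with an estimated correlation both lists were at an adjusted p of 0.0527. A scaling set by a few abundant genes is argued against, since the lowest macrophage median over 5 scalings was 1.99, against 2.07 as reported. Blood left in the vessel is argued against as far as red cells mark it. The macrophage mean rose 2.12 more than the erythroid mean (exact p = 0.00794, the smallest possible), and Hbb-bs was at 1960 ± 707 and 2559 ± 1840 CPM (SD, n = 5 each). Blood leukocytes that were more numerous, or stayed without red cells, would escape this test. Smooth muscle carried along in LCD is argued against, since with its list mean as a covariate the macrophage median was 2.29. The diet is a hypothesis beside others not tested here, such as a difference in dissection, flushing or processing between the groups. Whether more cells or more RNA per cell made the rise cannot be read from bulk tissue.

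The clock list passed camera, lower in HCD, with the preset correlation and passed fry (adjusted p = 0.00168), but not camera with an estimated correlation (0.181), 6 of its 11 genes fell, and 6 of 100 splits gave it as small a p. Less adipocyte RNA stays open. With the adipocyte covariate the clock median was -0.57, against -0.55, and 2 of the 6 calls were kept as the errors widened. The difference of list means was -0.47 (SE 0.10), against -0.43 (SE 0.07). The part of the adipocyte difference that the covariate took up therefore did not account for the lower clock list. That part was not the whole, since the white adipocyte mean still differed by -0.41 (SE 0.18) with the covariate, against -0.90 (SE 0.25) without it. For a shift in clock phase, as from another hour of dissection, a rise in the mean of Arntl, Clock and Npas2 was looked for. Their mean changed by 0.31 (SE 0.22, 95% interval -0.21 to 0.82, exact p = 0.198), which leaves such a shift open. A shift that does not raise this mean was not tested. Dilution by macrophage RNA is also open, since the clock change minus the endothelial change was -0.25 (exact p = 0.143). The diet is a further explanation, untested, and may act on the clock directly or on feeding time.

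The oxidative phosphorylation list passed camera, lower in HCD, with the preset correlation but not with an estimated one (adjusted p = 0.722) or by fry (0.199), 4 of its 92 genes fell, and 42 of 100 splits gave it as small a p. After the trend with gene length and GC content was removed the median was -0.23, against -0.32. Its bootstrap SE of 0.02 came from resampling the list's genes, which vary together (estimated correlation 0.643). That SE does not measure the spread between libraries, where the difference of list means had an SE of 0.20. How much of the fall length and GC content account for therefore stays open. Less adipocyte RNA could account for the lower list and stays open. With the adipocyte covariate the median was -0.040. The difference of list means went from -0.35 (SE 0.20) to -0.11 (SE 0.24), too wide to decide. Cfd and Pck1, white adipocyte markers that did not pass the gene test, were at 697 ± 308 and 598 ± 235 CPM in LCD and 379 ± 83.5 and 310 ± 99.96 CPM in HCD (SD, n = 5 each). Dilution by macrophage RNA stays open, since the change minus the endothelial change was -0.17 (exact p = 0.619).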

How the results depend on the processing

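The fits without HCD 1 and LCD 4 and with covariates were chosen after the data were seen; the other settings were planned. The 1916 changed genes (1385 higher, 531 lower) became 923 (817 and 106) at 2-fold or more, a stricter threshold by construction, and 988 (808 and 180) with the adipocyte covariate, which is itself lower in HCD. Fallen genes numbered 913 by the DESeq2 Wald test and 1011 with 1 surrogate variable. The DESeq2 fit was given 17553 genes, without the low-count filter of the main fit (13659 genes). Its simulated calls held more false ones, in counts drawn with edgeR's dispersion estimates, so that share need not hold for the real calls. The cause of the higher numbers was not tested. Other scalings, filters and limma-voom gave 1729 to 2321 changed genes, 2046 changed without HCD 1 and LCD 4, and no gene of the 1916 changed sign in any setting. Leaving out 1 library gave 1275 (without HCD 3) to 1989 changed genes, 1050 to 1466 higher and 225 to 594 lower; fallen genes were 350 without LCD 1, 347 without HCD 2, 225 without HCD 3 and 306 without HCD 4. Leaving out 1 library also gave 15 to 22 lists, 0 to 4 measures of library make-up (4 without HCD 1) and log2 fold changes of Ldlr from -0.63 to -0.12. With an estimated correlation 0 of the 18 lists passed camera (8 at an unadjusted p); by fry 12 of the 18 passed, and 2 others. Diets share replicate numbers but no label says that a number pairs libraries, and the deviations of same-numbered libraries correlated at -0.0850, -0.0799, 0.0659, 0.200 and 0.00286, with 1 of 5 matching its own number best. With the replicate block, 1556 genes changed (1183 higher, 373 lower; 1453 of them among the 1916) and 19 lists passed, cholesterol synthesis among them (adjusted p = 0.0458). Of the 84 named genes past the threshold, 53 stayed past it in every setting run, apart from the 2-fold threshold, which was not applied to them. The median log2 fold change of all tested genes was -0.056, and -0.106 with upper-quartile factors. At the depth reached, genes with fewer than about 10 counts in most libraries were not tested.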

Other observations

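The tests of macrophage kinds and the count of splits for each list were chosen after the results were seen. The rise was not shared by all macrophage genes: the general macrophage mean rose 2.50 more than the resident macrophage mean (exact p = 0.00794). This argues against an equal rise of every kind of macrophage only if the resident markers came mainly from macrophages, which was not tested. The foam cell mean rose 0.89 more than the general macrophage mean (exact p = 0.0397, unadjusted). A log2 rise is smaller where other cells already express a gene in LCD, to a degree that may differ between the lists. More macrophages of unchanged state therefore stay open as an explanation. A change in the mix or the state of the macrophages is a candidate explanation, as a hypothesis. Bulk RNA does not tell cells added from cells changed, and no cell counts, sorted cells or single-cell data were at hand to decide it. Of the 18 foam cell genes, 2 did not pass, Cd36 and Cd9, chosen after their values were seen.

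Of the 18 lists that passed camera with the preset correlation, none did with an estimated one (smallest adjusted p = 0.0527; 8 at an unadjusted p, and 12 by fry). Of these 18, 7 had a camera p that fewer than 5 of 100 splits reached, all higher in HCD: macrophage, foam cell, MHC class II, LXR and efflux, adhesion and Nrf2 genes (1 of 100 each, the real split; adjusted p = 0.181 and 0.225 for the last 2 with an estimated correlation) and inflammation (2). Cell cycle (9) and clock genes (6) came next. For the others the number of splits was 20 for white adipocyte, 28 for interferon, 28 for neutrophil, 29 for fatty acid oxidation, 32 for T cell, 39 for matrix, 42 for oxidative phosphorylation, 54 for smooth muscle and 57 for ribosomal protein genes. Every count of splits given for a list includes the real split.

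LCD 1 had the highest foam cell mean of its diet, 7.78 against 6.12 to 6.92 in the other LCD libraries and 9.53 to 10.32 in HCD. It also had the highest LCD values of Spp1 (92.9 CPM, the others 2.05 to 19.3), Il7r (16.7 CPM, the others 0.517 to 3.68), Cd4 (23.2 CPM, the others 0.512 to 8.78) and Cd22 (7.64 CPM, the others 0 to 1.19). Its general macrophage mean, 6.09, lay within the LCD range of 5.44 to 6.47. Its resident macrophage mean, 5.11, was the lowest of the 10 libraries.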
